A study of Mus musculus with 20 samples.

How the data were processed

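Tumour RNA was extracted with RNeasy midi columns, made into TruSeq RNA libraries and sequenced on a HiSeq4000, per the labels' protocols. Mice received 5 mg tamoxifen by gavage on 3 days at 8 to 10 weeks of age and were aged until morbidity, per the labels. Reads were aligned with HISAT2 2.0.4 to mm10 (GRCm38), per the submitters' processing notes. The counting tool, its annotation, its treatment of strand and of reads with several places in the genome, and the normalization are not given in the sources used here.

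The deposited table holds a signal value for 20636 Ensembl genes in 15 libraries, 5 each of KPT, KAT and KPAT. The authors' values are whole reads divided by a factor per library, judged from the values: multiplied by that factor, 100% of the deposited signal values fell within 0.01 of a whole number. The recovered depth was 14696138 to 26248484 reads per library. Counting error weighs most on genes near the minimum level. The other 5 samples of the series, the KT group, are not analysed here. Symbols and coordinates came from the GENCODE annotation of GRCm38, in which 20574 of the 20636 gene IDs matched a symbol.

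The design was fixed before the data were examined. It assumed normalized counts on the scale of reads, while the deposited values lie on the scale of CPM. Values were therefore multiplied by the geometric mean of reads per deposited unit over libraries, 19.478, so that the stated pseudocount of 1 and minimum mean of 10 keep their meaning. The same multiplier served every library and leaves the authors' scaling as it is. This left 16648 genes, and the version on the deposited scale was run as an alternative. The log2(normalized count + 1) values of all 15 libraries were fitted with limma 3.58.1 in R 4.3.3 (group means, eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05.

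Gene lists for cell types, pathways and neighbours of the targeted genes were fixed with the design, 42 in number, of which 40 had at least 5 tested genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated, and with fry. List levels per tumour were compared with exact two-sided permutation tests over all 252 assignments of 5 against 5. The genes named for each comparison followed a fixed rule. It took Trp53 and Cdkn2a, then up to 8 higher and 8 lower genes with the largest log2 fold change among those past the threshold, with at least 100 normalized counts in the higher group and no overlap between the groups. It passed over predicted genes, pseudogenes and receptor segments. It then took members with the smallest p in the list's direction, called or not, of up to 8 called lists. Lists described but not called gave up to 2 members. Called lists after the first 8 gave up to 2 members with the smallest p in either direction, chosen after the lists were seen. Sex-linked genes were not named. A gene and a list taken by these rules are not reported here.

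Alternatives fixed with the design were pseudocounts of 0.5 and 8, no minimum and a minimum mean of 50, median-of-ratios and quantile scaling, and fits of only the groups compared. Fixed as well were array weights, robust eBayes, the acinar, ductal or Y-linked level as a covariate, the replicate number as a block, leaving out each library, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 on the recovered reads. Alternatives chosen after seeing the data were the deposited scale, an exon length and GC correction, leaving out KPT 1 and KAT 1 (highest intestine and acinar levels), leaving out KPT 3, KAT 2 and KPAT 5 (most ribosomal RNA reads), and leaving out ribosomal protein genes and processed pseudogenes. Gene copies were found by shared 31-mers, with at least 20% shared between a processed pseudogene and its parent. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

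The model was tested on simulated data for the 16648 genes, with 250 changed genes per fold size over 5 runs. For KPAT against KPT it recovered 6.8% of genes changed 1.5-fold, 40.8% of those changed 2-fold, 67.6% at 4-fold and 84.8% at 8-fold. For KAT against KPT these shares were 7.2%, 39.6%, 66.4% and 87.2%, and for KPAT against KAT 6.4%, 43.2%, 68% and 89.2%. The general fibroblast list, shifted 2-fold in KPAT against KPT, was called in 5 of 5 runs, and 2 of 195 other list tests were called. Genes were drawn independently in these runs. In the tumours the estimated correlation was 0.62 within the general fibroblast list and 0.52 within the ribosomal protein list. The runs therefore do not measure how often camera at the preset correlation wrongly calls lists of correlated genes.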

Results

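RNA was sequenced from pancreatic ductal adenocarcinomas of mice in which tamoxifen switches on Cre recombinase in acinar cells, the enzyme-secreting cells of the pancreas (Ptf1aCreER). Cre activated a tdTomato reporter in every mouse. In KPT mice Trp53, the gene of the tumour suppressor p53, was floxed. In KAT mice the Cdkn2A-Arf locus was floxed instead, whose Arf product stabilises p53. In KPAT mice both genes were floxed. Each group holds 5 tumours that the labels number separately, and the whole tumour was profiled, so stroma, blood vessels and immune cells contribute RNA beside the cancer cells. The KT group, with neither suppressor floxed, is not analysed here.

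The libraries held 16622901 to 23039354 gene-assigned reads in KPT, 16704627 to 22124495 in KAT and 14696138 to 26248484 in KPAT. A total of 16648 genes passed the minimum level and were tested. Spearman correlations over genes ran from 0.934 to 0.989 within groups and from 0.903 to 0.973 between groups. The leading principal component held 25.9% of the variance and the next 16.7%. The library numbers of the 3 groups do not overlap, so a batch that follows them cannot be told apart from genotype. Expression levels below are mean ± SD over n = 5 tumours in deposited units (reads divided by a library factor). Fold changes are on the log2(normalized count + 1) scale with their SE, which understates the change of low genes, and adjusted p-values come from limma. Coordinates are from GRCm38 with the GENCODE annotation.

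The floxed genes were examined before any other. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) was at 24.3 ± 1.77 in KPT, 41.9 ± 9.53 in KPAT and 125 ± 20.03 in KAT, with no overlap between the 3 groups' tumours. KAT, whose Trp53 is intact, exceeded KPT (log2 fold change 2.35, SE 0.15, adjusted p = 3.10e-07), and KPAT fell below KAT (log2 fold change -1.58, SE 0.15, adjusted p = 6.05e-05). KPAT was above KPT, although Trp53 was floxed in both (log2 fold change 0.76, SE 0.15, adjusted p = 0.005596). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) was at 297 ± 47.1 in KPT, 426 ± 254 in KAT and 622 ± 289 in KPAT. None of its 3 comparisons passed, with adjusted p = 0.166 for KPAT against KPT, 0.696 for KAT against KPT and 0.608 for KPAT against KAT. The labels do not name the floxed exons, reads outside a floxed part check nothing about recombination, and cells that kept the alleles also give reads. For KAT against KPT the Cdkn2a log2 fold change of 0.25 turned negative in 3 alternative analyses, and with 1 library left out it ran from 0.01 (without KAT 2) to 0.56 (without KAT 4).

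**Figure D1:**
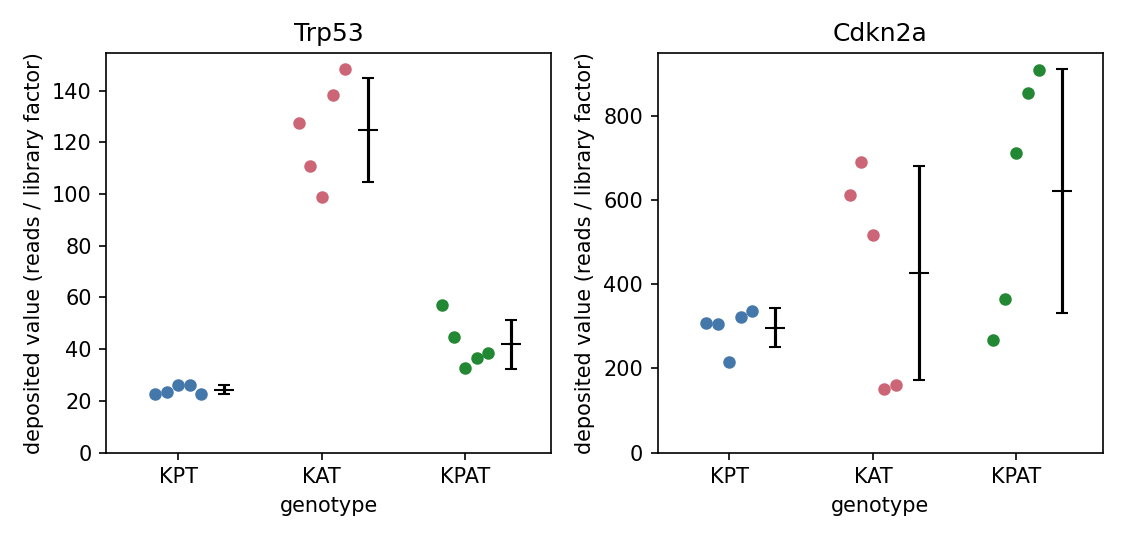
Deposited expression (reads divided by the library factor) of Trp53 and Cdkn2a, each point a tumour, bars the mean ± SD of 5 tumours per genotype. The KAT tumours hold the highest Trp53 values, with a mean of 125, while Cdkn2a overlaps between all 3 genotypes.

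KPAT against KPT asks what the floxed Arf allele adds where Trp53 is already floxed. Lists of matrix-producing fibroblast and of macrophage genes were higher in KPAT by camera at the preset correlation, and those of ribosomal protein and of hypoxia and glycolysis genes lower. With an estimated correlation none of these was called. Fry gave adjusted p = 0.00838 for general fibroblast, 0.0497 for macrophage, 0.0006 for ribosomal protein and 0.0224 for hypoxia and glycolysis genes. It did not call the type I interferon (0.276), neutrophil (0.1295) or tuft cell list (0.1245), which camera called at the preset correlation. Of 20 general fibroblast and matrix genes, 15 rose and 5 did not pass (median log2 fold change 1.51, camera adjusted p = 2.93e-10, adjusted p = 0.492 with an estimated correlation). Of 22 ribosomal protein genes, 18 fell and 4 did not pass (median log2 fold change -0.66, camera adjusted p = 7.03e-15, adjusted p = 0.492 with an estimated correlation). In all, 2752 genes passed at adjusted p 0.05, 1520 higher and 1232 lower in KPAT. A log2 fold change of at least 1 in size was reached by 855 of the higher and 312 of the lower genes, and 5368 genes had an unadjusted p below 0.05. edgeR called 2731 genes and DESeq2 3911. Without KPAT 2 the count was 1686, and a model of these 2 groups alone gave 1811. On the deposited scale the calls split into 1012 higher and 1108 lower.

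The stromal genes of KPAT included fibrillar and filamentous collagens. Col5a2 was at 589 ± 171 in KPAT against 193 ± 73.4 in KPT (log2 fold change 1.67, SE 0.27, adjusted p = 0.00286). Col6a3 was at 194 ± 70.1 in KPAT against 41.8 ± 18.7 in KPT (log2 fold change 2.3, SE 0.38, adjusted p = 0.00289). Col1a2, a chain of type I collagen, was at 2518 ± 915 in KPAT against 716 ± 288 in KPT (log2 fold change 1.86, SE 0.33, adjusted p = 0.00374). The mean level of the list, a mean over genes of log2(normalized count + 1), was 12.66 ± 0.57 in KPAT and 11.14 ± 0.76 in KPT (exact two-sided permutation p = 0.00794, 0.0529 after adjustment over lists). Adjusted over the list alone, 18 of these genes rose. Of 16 genes of myofibroblastic cancer-associated fibroblasts, 8 rose and 8 did not pass (median log2 fold change 1.15, camera adjusted p = 0.000796, adjusted p = 0.492 with an estimated correlation). They included Postn, the matricellular protein periostin, at 368 ± 57.4 in KPAT against 131 ± 43.2 in KPT (log2 fold change 1.54, SE 0.21, adjusted p = 0.00154). Tnc, which encodes tenascin C, was at 662 ± 277 in KPAT against 174 ± 83.8 in KPT (log2 fold change 2.06, SE 0.5, adjusted p = 0.0138). Adjusted over the list alone, 10 of them rose and 1 fell. Of 17 mesenchymal genes, 7 rose, 10 adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 0.0002199, adjusted p = 0.492 with an estimated correlation). The transcription factor gene Snai1 was at 33.4 ± 14.1 in KPAT against 7.31 ± 2.69 in KPT (log2 fold change 2.2, SE 0.35, adjusted p = 0.00248). Zeb1, another such factor, was at 33.6 ± 3.21 in KPAT against 19.04 ± 4.35 in KPT (log2 fold change 0.84, SE 0.16, adjusted p = 0.00523).

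Other matrix groups moved the same way. Among 18 TGF-beta response genes 7 rose, 9 adjusted over the list alone with 1 lower (median log2 fold change 0.5, camera adjusted p = 0.00481, adjusted p = 0.492 with an estimated correlation). Tgfbr2, a receptor of the pathway, was at 279.7 ± 50.01 in KPAT against 131 ± 32.7 in KPT (log2 fold change 1.11, SE 0.2, adjusted p = 0.00436). Among 20 basement membrane genes 8 rose, and 8 adjusted over the list alone (median log2 fold change 0.43, camera adjusted p = 0.007104, adjusted p = 0.492 with an estimated correlation). The laminin chain gene Lama4 was at 59.8 ± 21.9 in KPAT against 23.9 ± 6.97 in KPT (log2 fold change 1.3, SE 0.27, adjusted p = 0.00736). Among 24 matrix remodelling proteases 7 rose, 11 adjusted over the list alone with 1 lower (median log2 fold change 0.59, camera adjusted p = 0.0144, adjusted p = 0.492 with an estimated correlation). Mmp19 was at 30.1 ± 5.25 in KPAT against 10.5 ± 2.202 in KPT (log2 fold change 1.53, SE 0.2, adjusted p = 0.00126). That list lost its call without KPT 3 (median 0.45, adjusted p = 0.0518) or KPAT 2 (0.53, 0.05299). The protease list's adjusted p ran from 0.00228 to 0.05299 over the alternatives at the preset correlation. Of 18 inflammatory fibroblast genes only Ccl7, a monocyte-attracting chemokine, and Has1, a hyaluronan synthase, rose, 1 adjusted over the list alone (median log2 fold change 0.69, camera adjusted p = 0.0201, adjusted p = 0.492 with an estimated correlation). Ccl7 was at 4.06 ± 1.88 in KPAT against 0.596 ± 0.433 in KPT (log2 fold change 2.79, SE 0.55, adjusted p = 0.00611). The call of this list ended without KPT 3 (median 0.6, adjusted p = 0.0591) or KPAT 2 (0.53, 0.0712), and that of Has1 without KPT 1, KPT 2, KPT 3, KPT 4, KAT 1, KAT 2, KAT 4, KAT 5, KPAT 2, KPAT 3, KPAT 4 or KPAT 5 (adjusted p up to 0.113). The inflammatory fibroblast list's adjusted p ran from 0.005997 to 0.0712 over the alternatives at the preset correlation.

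Of 24 macrophage and monocyte genes, 10 rose and 14 did not pass, with 10 adjusted over the list alone (median log2 fold change 0.62, camera adjusted p = 0.000796, adjusted p = 0.583 with an estimated correlation). Ccr2, the chemokine receptor of monocytes, was at 23.1 ± 3.84 in KPAT against 3.66 ± 2.58 in KPT (log2 fold change 2.86, SE 0.41, adjusted p = 0.001901). Trem2, a receptor of lipid-associated macrophages, was at 19.9 ± 4.62 in KPAT against 10.4 ± 2.92 in KPT (log2 fold change 0.94, SE 0.21, adjusted p = 0.0106). The macrophage level was 9.36 ± 0.47 in KPAT and 8.73 ± 0.41 in KPT (exact two-sided permutation p = 0.0635, 0.179 after adjustment over lists). The neutrophil list was lower (median log2 fold change -1.0, camera adjusted p = 0.0186, adjusted p = 0.677 with an estimated correlation), with 1 of 20 genes higher and 2 lower. Adjusted over the list alone the counts were 1 and 3. Of the lower genes, Retnlg (-2.68 ± 0.81) lost its call without KPT 1, KPT 2, KPT 5, KPAT 1, KPAT 2 or KPAT 5 (adjusted p up to 0.0882). Asprv1 (-1.52 ± 0.5) lost it in each fit that left out a library other than KPT 3 or KPAT 4 (adjusted p up to 0.119). The list itself was not called without KPT 3 (median -1.01, adjusted p = 0.0532), KPT 5 (-0.95, 0.0508) or KPAT 5 (-0.82, 0.104). The neutrophil list's adjusted p ran from 0.00239 to 0.539 over the alternatives at the preset correlation. Of 13 tuft cell genes, markers of a chemosensory epithelial cell, Hpgds and Bmx rose, and 2 adjusted over the list alone (median log2 fold change 0.98, camera adjusted p = 0.0186, adjusted p = 0.677 with an estimated correlation). Hpgds, which makes prostaglandin D, was at 7.22 ± 2.56 in KPAT against 2.39 ± 1.01 in KPT (log2 fold change 1.59, SE 0.35, adjusted p = 0.00916). The tuft list was not called without KPT 4, KPT 5, KPAT 1 or KPAT 2 (adjusted p up to 0.0834), and its median was 1.52 without KPAT 5.

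Among the genes that fell, 13 of 20 hypoxia and glycolysis genes were lower and 7 did not pass, with 16 lower adjusted over the list alone (median log2 fold change -1.15, camera adjusted p = 3.10e-09, adjusted p = 0.492 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, was at 22.9 ± 11.5 in KPAT against 216 ± 120.5 in KPT (log2 fold change -3.1, SE 0.6, adjusted p = 0.00562). Bnip3, a mitochondrial protein induced by low oxygen, was at 11.7 ± 3.59 in KPAT against 80.4 ± 44.8 in KPT (log2 fold change -2.61, SE 0.54, adjusted p = 0.00758). The glycolytic enzyme gene Pgk1 was at 251 ± 62.3 in KPAT against 778 ± 182 in KPT (log2 fold change -1.63, SE 0.34, adjusted p = 0.00758). Among ribosomal protein genes, Rpl5 was at 724 ± 48.1 in KPAT against 1388 ± 199 in KPT (log2 fold change -0.93, SE 0.11, adjusted p = 0.00113). Rpl19 was at 241 ± 27.7 in KPAT against 478 ± 133 in KPT (log2 fold change -0.95, SE 0.15, adjusted p = 0.00281). Rplp0 was at 750.3 ± 34.3 in KPAT against 2015 ± 725 in KPT (log2 fold change -1.34, SE 0.21, adjusted p = 0.00248), an uncertain value because its near-identical copy Gm8730 can take its reads. Summed with Gm8730 its log2 fold change was -0.69, and with Gm9625 added -0.61. Of 18 immediate early and stress genes 5 fell, 8 adjusted over the list alone (median log2 fold change -0.65, camera adjusted p = 0.000796, adjusted p = 0.492 with an estimated correlation). The stress transcription factor gene Ddit3 was at 10.6 ± 1.76 in KPAT against 32.2 ± 13.2 in KPT (log2 fold change -1.48, SE 0.31, adjusted p = 0.00736). Of 20 ductal epithelium genes only 3 fell, 2 adjusted over the list alone (median log2 fold change -0.46, camera adjusted p = 0.00451, adjusted p = 0.492 with an estimated correlation). Among them Elf3 (-1.69 ± 0.48) was not called without KPT 1, KPT 2, KPAT 3 or KPAT 5 (adjusted p up to 0.0713), nor Cldn7 (-0.85 ± 0.25) without KPT 1, KPT 3, KPAT 2, KPAT 4 or KPAT 5 (up to 0.0707). Of 25 type I interferon genes 3 fell, and 3 adjusted over the list alone (median log2 fold change -1.34, camera adjusted p = 0.000796, adjusted p = 0.776 with an estimated correlation). Mx2, an antiviral GTPase, was at 1.28 ± 1.72 in KPAT against 9.28 ± 11 in KPT (log2 fold change -2.85, SE 0.72, adjusted p = 0.0165). The interferon median was -0.75 without KPT 5 and -2.1 without KPAT 1. With the ductal level as a covariate it turned positive (0.22, adjusted p = 0.966) while camera's direction stayed lower, and over the alternatives at the preset correlation its adjusted p ran from 1.01e-08 to 0.966.

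The naming rule kept only genes without overlap between the groups and with at least 100 normalized counts in the higher one. Among the higher genes it took, Cep85 (ENSMUSG00000037443, chromosome 4, 134129858 to 134187112), a centrosome gene, was at 1360.5 ± 645 in KPAT against 51.2 ± 53.9 in KPT (log2 fold change 5.02, SE 0.47, adjusted p = 0.000336). Camk2b, a subunit of calcium/calmodulin-dependent kinase II, was at 16.01 ± 8.33 in KPAT against 0.644 ± 0.451 in KPT (log2 fold change 4.48, SE 0.55, adjusted p = 0.00126). Cnbd2 was at 37.8 ± 26.2 in KPAT against 1.58 ± 0.438 in KPT (log2 fold change 4.08, SE 0.55, adjusted p = 0.00151). Sfrp1, a secreted Wnt antagonist, was at 261 ± 244 in KPAT against 25.99 ± 14.9 in KPT (log2 fold change 3.3, SE 0.71, adjusted p = 0.00863). Dio2, which activates thyroid hormone, had a log2 fold change of 3.54 ± 0.84, and St8sia2, a polysialyltransferase, 3.48 ± 0.74. Mcpt8, a basophil protease (3.68 ± 0.8), and Raet1e, a stress ligand (3.4 ± 1.01), belong to families of similar copies, so their counts are uncertain. The Raet1e call ended without KPT 1, KPT 3, KPT 5, KPAT 3, KPAT 4 or KPAT 5 (adjusted p up to 0.075).

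In the other direction, Muc3, an intestinal membrane mucin, was at 2.84 ± 3.79 in KPAT against 220.0 ± 229 in KPT (log2 fold change -7.03, SE 1.7, adjusted p = 0.0138). Cdx2, the intestinal transcription factor, was at 0.645 ± 0.702 in KPAT against 25.6 ± 28.4 in KPT (log2 fold change -5.0, SE 1.3, adjusted p = 0.0185). Cdhr5, a brush border cadherin, was at 2.89 ± 1.71 in KPAT against 66.6 ± 79.1 in KPT (log2 fold change -4.3, SE 1.28, adjusted p = 0.0335). KPT 1 held the highest value of each of these genes among KPT tumours, and its level of the intestine list was 10.02 against 3.45 to 4.42 in the other 4 KPT tumours. Foxa1, an endoderm transcription factor (chromosome 12, 57540628 to 57546916), was at 7.75 ± 7.09 in KPAT against 80.8 ± 66.7 in KPT (log2 fold change -3.39, SE 0.71, adjusted p = 0.00801), and its neighbour Ttc6 (chromosome 12, 57564113 to 57737928) at 1.44 ± 1.28 in KPAT against 11.8 ± 4.05 in KPT (log2 fold change -3.46, SE 0.71, adjusted p = 0.007298). Rgs1 (-3.62 ± 0.72), a regulator of G protein signalling in leukocytes, Fam71f2 (-3.26 ± 0.64) and Acan (-3.1 ± 0.97), the proteoglycan aggrecan, were also lower. The call of Cdhr5 ended without KPT 1, KPT 3, KPAT 3 or KPAT 5 (adjusted p up to 0.085), and that of Acan without KPT 1, KPT 2, KPT 3, KPT 4, KPT 5, KPAT 1, KPAT 3, KPAT 4 or KPAT 5 (up to 0.0974). Without KPT 3, KAT 2 and KPAT 5, Cdx2 (-4.9, adjusted p = 0.0684; 0.00248 to 0.0684 over all alternatives) and Mx2 were not called, nor were Cdhr5, Acan and Raet1e. With the ductal level as a covariate, 25 of 83 named genes were no longer called, among them Dio2, Raet1e, Muc3, Cdhr5, Acan, Mx2, Elf3, Cldn7, Retnlg, Asprv1 and Has1. The neutrophil, interferon and ductal lists also lost their calls, the ductal list by the construction of this covariate.

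**Figure D2:**
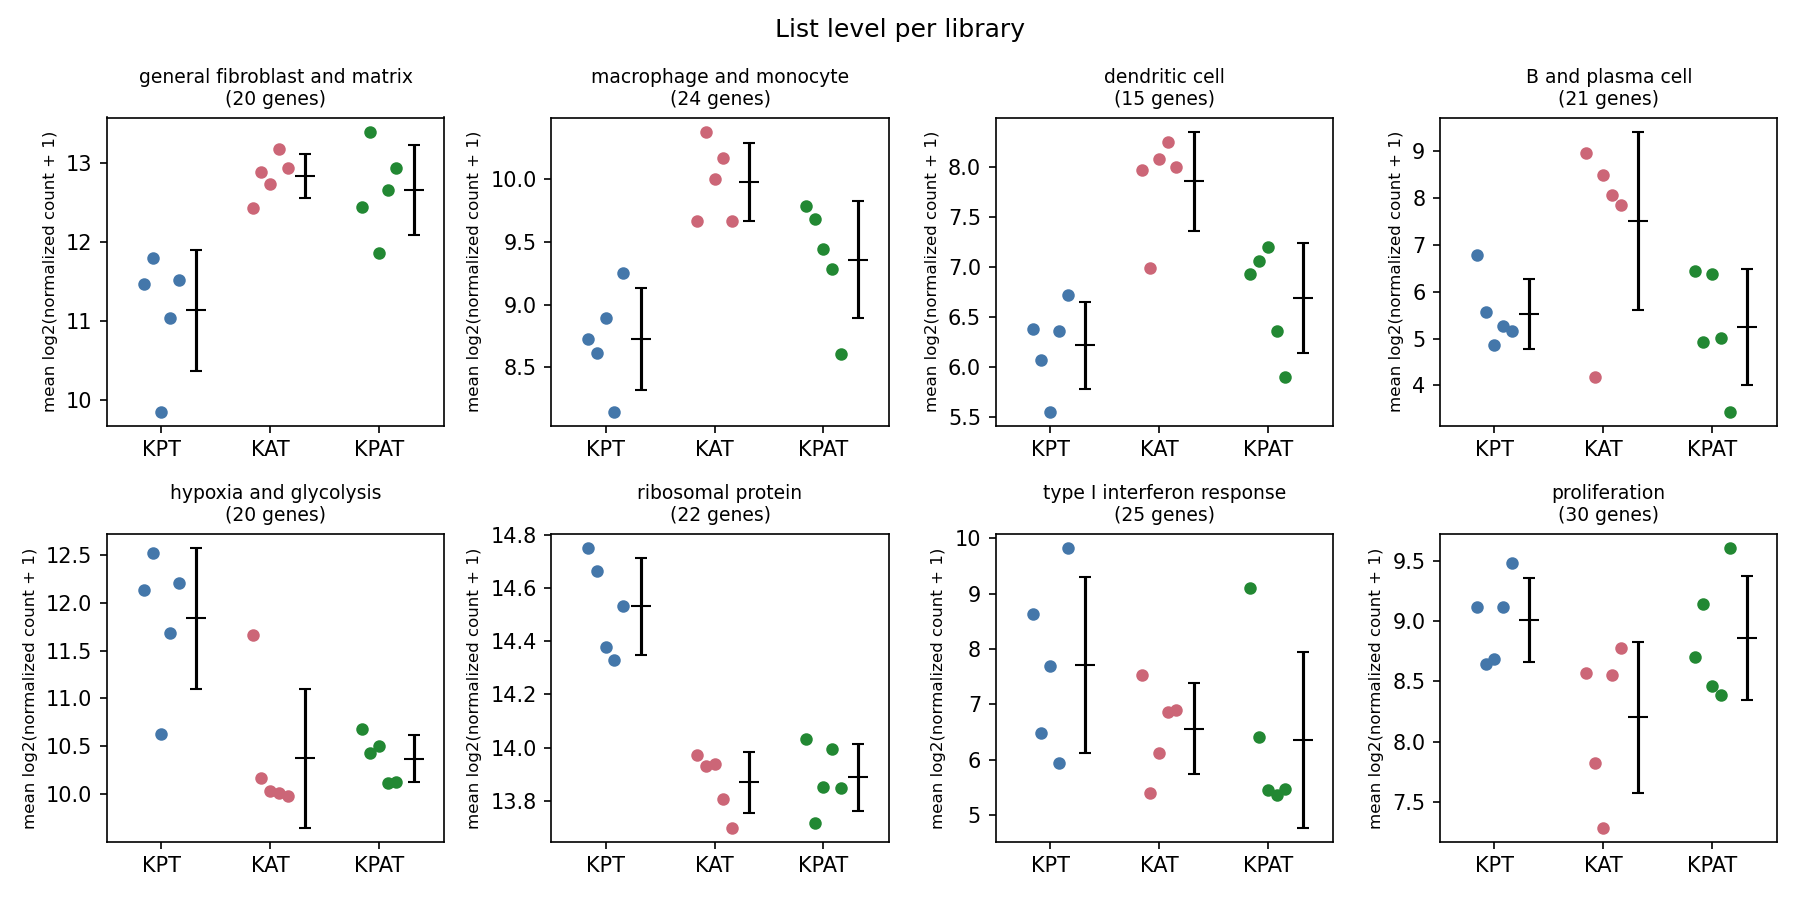
Level of 8 gene lists per tumour, the mean of log2(normalized count + 1) over the tested genes of each list, with bars for the mean ± SD of 5 tumours per genotype. The ribosomal protein and the hypoxia and glycolysis mean levels are lower in KAT and KPAT than in KPT, with KAT 1 at 11.67 for hypoxia apart from the other KAT tumours, and the B and plasma cell level of KAT 2 is 4.18.

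KAT against KPT sets the floxed Arf allele against the floxed Trp53 allele, each without the other. By camera at the preset correlation, the lists of fibroblast, macrophage, dendritic and tuft cell genes were higher in KAT, and those of ribosomal protein, hypoxia and glycolysis, and proliferation genes lower. None of these calls held with an estimated correlation. Fry gave adjusted p = 0.00318 for general fibroblast, 0.00128 for macrophage, 0.00075 for dendritic and 0.0106 for tuft cell genes. For ribosomal protein, hypoxia and glycolysis, and proliferation genes it gave 0.000234, 0.00918 and 0.0479. Fry did not call the B and plasma cell (0.0628), antigen presentation (0.123), type I interferon (0.321) or gastric list (0.112), which camera called at the preset correlation. All 20 general fibroblast and matrix genes rose, all 20 also adjusted over the list alone (median log2 fold change 1.64, camera adjusted p = 1.01e-08, adjusted p = 0.405 with an estimated correlation), and 10 of 15 dendritic cell genes rose (median log2 fold change 1.86, camera adjusted p = 0.000415, adjusted p = 0.405 with an estimated correlation). In all, 4805 genes passed, 2599 higher and 2206 lower in KAT. A log2 fold change of at least 1 in size was reached by 1774 higher and 530 lower genes, and 6857 genes had an unadjusted p below 0.05. edgeR called 4732 genes and DESeq2 6021. On the deposited scale, which keeps only genes with a mean of at least 10 there, the calls split into 1382 higher and 1908 lower. Lower calls also outnumbered higher ones after quantile normalization (2431 against 1999) and with the stricter minimum level (2112 against 2062).

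Among matrix genes, Fbn1, which encodes fibrillin, was at 417 ± 98.98 in KAT against 106 ± 48.3 in KPT (log2 fold change 2.13, SE 0.36, adjusted p = 0.00105). Col6a3 was at 181 ± 66.4 in KAT against 41.8 ± 18.7 in KPT (log2 fold change 2.18, SE 0.38, adjusted p = 0.00113). The fibroblast level was 12.83 ± 0.27 in KAT and 11.14 ± 0.76 in KPT (exact two-sided permutation p = 0.00794, 0.0353 after adjustment over lists). Of 16 myofibroblastic genes 10 rose, 11 adjusted over the list alone (median log2 fold change 1.32, camera adjusted p = 0.000128, adjusted p = 0.405 with an estimated correlation). The fibril-associated collagen gene Col12a1 was at 707 ± 277 in KAT against 155 ± 63.2 in KPT (log2 fold change 2.22, SE 0.36, adjusted p = 0.000803). Of 18 inflammatory fibroblast genes 6 rose, and 6 adjusted over the list alone (median log2 fold change 1.21, camera adjusted p = 0.00317, adjusted p = 0.405 with an estimated correlation). Svep1 was at 82.6 ± 48.6 in KAT against 12.2 ± 6.82 in KPT (log2 fold change 2.77, SE 0.63, adjusted p = 0.00539). Of 18 TGF-beta response genes 8 rose and 1 fell, 12 and 1 adjusted over the list alone (median log2 fold change 0.63, camera adjusted p = 0.00101, adjusted p = 0.405 with an estimated correlation). The matrix protein gene Tgfbi was at 174 ± 36.7 in KAT against 66.4 ± 17.7 in KPT (log2 fold change 1.4, SE 0.18, adjusted p = 0.000233). Of 17 mesenchymal genes 8 rose, and 8 adjusted over the list alone (median log2 fold change 0.75, camera adjusted p = 0.00418, adjusted p = 0.405 with an estimated correlation). Zeb2 was at 56.4 ± 9.94 in KAT against 22.5 ± 5.09 in KPT (log2 fold change 1.34, SE 0.21, adjusted p = 0.000686). The mesenchymal call ended with the ductal level as a covariate.

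Of 24 matrix remodelling proteases 10 rose and 1 fell, 15 and 2 adjusted over the list alone (median log2 fold change 0.73, camera adjusted p = 0.00482, adjusted p = 0.405 with an estimated correlation). Their inhibitor Timp3, part of this list, was at 497 ± 169.7 in KAT against 128 ± 62.3 in KPT (log2 fold change 2.02, SE 0.38, adjusted p = 0.00172). Of 12 pericyte and smooth muscle genes 6 rose, and 6 adjusted over the list alone (median log2 fold change 1.09, camera adjusted p = 0.00574, adjusted p = 0.485 with an estimated correlation). The pericyte receptor gene Pdgfrb was at 143 ± 35.7 in KAT against 48.9 ± 11.5 in KPT (log2 fold change 1.55, SE 0.21, adjusted p = 0.000326). Of 17 endothelial genes 8 rose, 10 adjusted over the list alone (median log2 fold change 0.89, camera adjusted p = 0.00223, adjusted p = 0.522 with an estimated correlation). The VEGF receptor gene Kdr was at 52.1 ± 20.8 in KAT against 19.8 ± 5.21 in KPT (log2 fold change 1.34, SE 0.28, adjusted p = 0.00325). The endothelial level was 9.66 ± 0.53 in KAT and 8.98 ± 0.4 in KPT (exact two-sided permutation p = 0.0397, 0.0794 after adjustment over lists). Of 20 basement membrane genes 6 rose, and 6 adjusted over the list alone (median log2 fold change 0.45, camera adjusted p = 0.0179, adjusted p = 0.405 with an estimated correlation). That call ended without KPT 4 (median 0.34, adjusted p = 0.0523) or KAT 2 (0.52, 0.0801), with the ductal covariate and after the exon length and GC correction. The basement membrane list's adjusted p ran from 0.000284 to 0.158 over the alternatives at the preset correlation.

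Several immune lists were higher in KAT, but the neutrophil list was not called (median -0.53, camera adjusted p = 0.482), with 2 of 20 genes higher and 2 lower. Of 24 macrophage and monocyte genes 14 rose, 15 adjusted over the list alone (median log2 fold change 1.28, camera adjusted p = 2.07e-07, adjusted p = 0.405 with an estimated correlation). Ccr2 was at 51.5 ± 27.2 in KAT against 3.66 ± 2.58 in KPT (log2 fold change 3.86, SE 0.41, adjusted p = 9.22e-05). Csf1r, the receptor that macrophages need for survival, was at 206 ± 63.6 in KAT against 61.6 ± 9.94 in KPT (log2 fold change 1.7, SE 0.24, adjusted p = 0.000382). The macrophage level was 9.98 ± 0.31 in KAT and 8.73 ± 0.41 in KPT (exact two-sided permutation p = 0.00794, 0.0353 after adjustment over lists). Among dendritic cell genes, with 10 higher adjusted over the list alone, Ccl17, a chemokine for T cells, was at 34.4 ± 13.2 in KAT against 3.91 ± 2.56 in KPT (log2 fold change 3.35, SE 0.6, adjusted p = 0.00136). Wdfy4, needed for cross-presentation, was at 21.8 ± 4.83 in KAT against 5.896 ± 0.678 in KPT (log2 fold change 1.86, SE 0.27, adjusted p = 0.000435). Of 21 B and plasma cell genes 5 rose, 4 adjusted over the list alone (median log2 fold change 1.76, camera adjusted p = 0.00102, adjusted p = 0.522 with an estimated correlation), among them Cd22 at 8.87 ± 4.66 in KAT against 2.103 ± 0.713 in KPT (log2 fold change 1.97, SE 0.38, adjusted p = 0.00235). Their median was 2.71 without KAT 2, whose level lay below that of every KPT tumour. The B and plasma cell level was 7.51 ± 1.91 in KAT and 5.53 ± 0.75 in KPT (exact two-sided permutation p = 0.0714, 0.1099 after adjustment over lists). Of 21 T cell genes only Trac and Pdcd1 rose, 0 adjusted over the list alone (median log2 fold change 1.51, camera adjusted p = 0.00482, adjusted p = 0.522 with an estimated correlation). Trac was not called without KAT 3 (1.93, adjusted p = 0.05496) or KAT 4 (1.92, 0.0576; 0.00256 to 0.0608 over all alternatives), and Pdcd1 (2.03 ± 0.7) without KPT 2, KPT 3, KPT 4, KAT 1, KAT 3, KAT 4 or KAT 5 (adjusted p up to 0.0987). Both calls also ended after quantile normalization and with only these groups fitted. The T cell list was not called with a stricter minimum level, nor the B and plasma cell list on the deposited scale.

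Of 25 antigen presentation genes 8 rose, 10 adjusted over the list alone (median log2 fold change 0.68, camera adjusted p = 0.00635, adjusted p = 0.646 with an estimated correlation). H2-DMa, which loads peptides on MHC class II, was at 59.1 ± 22 in KAT against 14.6 ± 2.87 in KPT (log2 fold change 1.96, SE 0.34, adjusted p = 0.00116). This list's call ended without KAT 1 (median 0.49, adjusted p = 0.0598). Its adjusted p ran from 1.05e-07 to 0.0598 over the alternatives at the preset correlation. Its median was 1.03 without KPT 1, 0.44 without KPT 4 and 1.02 without KAT 2. Of 13 tuft cell genes 7 rose, and 7 adjusted over the list alone (median log2 fold change 2.14, camera adjusted p = 0.00107, adjusted p = 0.417 with an estimated correlation). Alox5, which starts leukotriene synthesis, was at 33.5 ± 18.8 in KAT against 5.94 ± 1.04 in KPT (log2 fold change 2.28, SE 0.46, adjusted p = 0.00269). Of 18 endocrine and enteroendocrine genes 5 rose, 7 adjusted over the list alone (median log2 fold change 2.29, camera adjusted p = 0.00107, adjusted p = 0.522 with an estimated correlation). The islet transcription factor gene Isl1 was at 2.503 ± 1.398 in KAT against 0.419 ± 0.1797 in KPT (log2 fold change 2.34, SE 0.47, adjusted p = 0.00256).

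Ribosomal protein genes again formed the lower group with the smallest camera p, 19 of 22 falling, and 19 adjusted over the list alone (median log2 fold change -0.7, camera adjusted p = 5.68e-12, adjusted p = 0.405 with an estimated correlation). Rpl5 was at 717 ± 41.9 in KAT against 1388 ± 199 in KPT (log2 fold change -0.94, SE 0.11, adjusted p = 0.000168). Rpl8 was at 814 ± 60.8 in KAT against 1457 ± 210.0 in KPT (log2 fold change -0.83, SE 0.12, adjusted p = 0.000359). Of 20 hypoxia and glycolysis genes 16 fell, and 16 adjusted over the list alone (median log2 fold change -1.23, camera adjusted p = 1.41e-07, adjusted p = 0.405 with an estimated correlation). The aldolase gene Aldoa was at 490.3 ± 279 in KAT against 1178 ± 269.7 in KPT (log2 fold change -1.37, SE 0.27, adjusted p = 0.002398). Pdk1, which limits pyruvate entry into mitochondria, was at 43.96 ± 24.1 in KAT against 108 ± 31.8 in KPT (log2 fold change -1.38, SE 0.27, adjusted p = 0.00242). KAT 1 stood at 11.67 for this list and the other 4 KAT tumours at 9.98 to 10.17. Of 30 proliferation genes 9 fell, 12 adjusted over the list alone (median log2 fold change -0.85, camera adjusted p = 1.57e-05, adjusted p = 0.505 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was at 13.8 ± 1.28 in KAT against 47.5 ± 21.3 in KPT (log2 fold change -1.68, SE 0.3, adjusted p = 0.00139). Birc5, which encodes survivin, was at 8.77 ± 4.24 in KAT against 19.5 ± 3.801 in KPT (log2 fold change -1.31, SE 0.39, adjusted p = 0.02097). The Birc5 call ended with array weights and with the ductal covariate. Of 18 immediate early and stress genes 8 fell, 11 adjusted over the list alone with 1 higher (median log2 fold change -0.81, camera adjusted p = 0.000518, adjusted p = 0.405 with an estimated correlation). The heat shock gene Dnajb1 was at 48.9 ± 7.27 in KAT against 92.1 ± 19.2 in KPT (log2 fold change -0.9, SE 0.19, adjusted p = 0.00404).

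Epithelial and interferon lists gave weaker results. Of 20 ductal genes 6 fell, and 6 adjusted over the list alone (median log2 fold change -0.45, camera adjusted p = 0.00482, adjusted p = 0.405 with an estimated correlation). The keratin gene Krt18 was at 1535 ± 639 in KAT against 2995 ± 652 in KPT (log2 fold change -1.02, SE 0.26, adjusted p = 0.0102). The ductal call ended after quantile normalization and with array weights. Of 27 gastric metaplasia genes 5 fell and 1 rose, 4 and 1 adjusted over the list alone (median log2 fold change -0.61, camera adjusted p = 0.0251, adjusted p = 0.522 with an estimated correlation). Vsig1, a stomach junction protein, was at 30.6 ± 15.1 in KAT against 114 ± 22.1 in KPT (log2 fold change -2.05, SE 0.37, adjusted p = 0.00137). Without KPT 1 (median -0.43, adjusted p = 0.1102) or KAT 3 (-0.51, 0.0921) the gastric list was not called. Its adjusted p ran from 0.00478 to 0.962 over the alternatives at the preset correlation. Of 25 type I interferon genes 3 fell, and 3 adjusted over the list alone (median log2 fold change -1.09, camera adjusted p = 0.0103, adjusted p = 0.652 with an estimated correlation). Xaf1 was at 6.46 ± 2.23 in KAT against 33.6 ± 24.4 in KPT (log2 fold change -2.17, SE 0.54, adjusted p = 0.00883). The interferon list was not called without KPT 5 (median -0.43, adjusted p = 0.167) or KAT 2 (-0.68, 0.0703), and its median was -1.64 without KPT 4. Its adjusted p ran from 0.000832 to 0.386 over the alternatives at the preset correlation. With the ductal covariate the gastric and interferon medians turned positive and neither list was called.

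Of 28 p53 target genes 8 rose and 2 fell in KAT, the group with intact Trp53, with the same counts adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 0.0432, adjusted p = 0.427 with an estimated correlation). Ak1, an adenylate kinase gene, was at 43.5 ± 6.14 in KAT against 16.4 ± 3.26 in KPT (log2 fold change 1.41, SE 0.21, adjusted p = 0.000423). Eda2r, a death receptor gene, was at 6.34 ± 2.09 in KAT against 1.44 ± 1.11 in KPT (log2 fold change 2.34, SE 0.44, adjusted p = 0.00181). The p53 target call ended without KPT 3 (median 0.17, adjusted p = 0.156), KAT 1 (0.28, 0.0598), KAT 2 (0.22, 0.0876) or KAT 3 (0.26, 0.0681), and in 6 of the other alternatives. This list's adjusted p ran from 0.0141 to 0.279 over the alternatives at the preset correlation. No list call of any of the 3 comparisons held when camera estimated the correlation between genes.

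The higher genes that the naming rule took included tuft cell genes. Sh2d7, an adaptor of tuft cells (chromosome 9, 54538984 to 54545020), was at 14.7 ± 14.7 in KAT against 0.203 ± 0.202 in KPT (log2 fold change 5.71, SE 1.26, adjusted p = 0.00447). Rgs13 was at 14.8 ± 16.4 in KAT against 0.342 ± 0.401 in KPT (log2 fold change 5.16, SE 1.42, adjusted p = 0.01495). Spib, a transcription factor of lymphoid and tuft cells, was at 20.8 ± 15.4 in KAT against 0.787 ± 0.594 in KPT (log2 fold change 4.47, SE 1.14, adjusted p = 0.00999). Camk2b (5.45 ± 0.55) and Sfrp1 (4.13 ± 0.71) were again among them, beside the matrix gene Abi3bp (4.03 ± 0.79). Retnla (4.6 ± 0.73), a product of alternatively activated macrophages, and Bglap3 (4.13, adjusted p = 0.0138) belong to families of similar copies and are uncertain.

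The lower genes included mucosal markers. Muc5b, a secreted airway mucin, was at 0.625 ± 0.496 in KAT against 85.2 ± 113 in KPT (log2 fold change -5.43, SE 1.22, adjusted p = 0.00497), Cldn18, a gastric tight junction protein, at 15.05 ± 12.3 in KAT against 427 ± 572 in KPT (log2 fold change -4.74, SE 1.04, adjusted p = 0.00429). Psca, a surface antigen of pancreatic cancer, was at 33.7 ± 27.1 in KAT against 276 ± 109.6 in KPT (log2 fold change -4.05, SE 0.99, adjusted p = 0.00836). Nrn1 (-5.17 ± 0.66), Acan (-6.01 ± 0.97) and Ttc6 (-4.67 ± 0.71) also fell. Eno1b (chromosome 18, 48045335 to 48048412) was at 24.2 ± 53.4 in KAT against 205 ± 63.8 in KPT (log2 fold change -7.43, SE 1.8, adjusted p = 0.007895), an uncertain value because it shares sequence with the enolase gene Eno1, and neither edgeR nor DESeq2 called it. With the ductal covariate 15 of 95 named genes lost their calls, Cldn18 and Psca among them.

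Of the 2752 genes called in KPAT and the 4805 called in KAT, each against KPT, 2249 were called in both and in the same direction, 1240 higher and 1009 lower than KPT. Called in opposite directions were 0. Independent lists of these sizes would share 237 higher and 163 lower genes. The log2 fold changes of both comparisons correlated across genes, which are not independent replicates, at 0.772 with a covariance of 0.578. Simulated unchanged groups against the same 5 KPT libraries gave a mean correlation of 0.499, a mean covariance of 0.0946 and at most 0 shared genes in 50 simulations. The simulated genes varied independently, so the count of 0 does not measure what shared controls can give among correlated genes. Other splits of the real KPAT and KPT tumours called up to 494 genes. When KPT was split so that each comparison had its own controls, 20 fits shared between 137 and 910 genes, with a median of 707.5, a median correlation of 0.57 and a median covariance of 0.476. Without KPAT 2 the shared count was 1463.

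**Figure D3:**
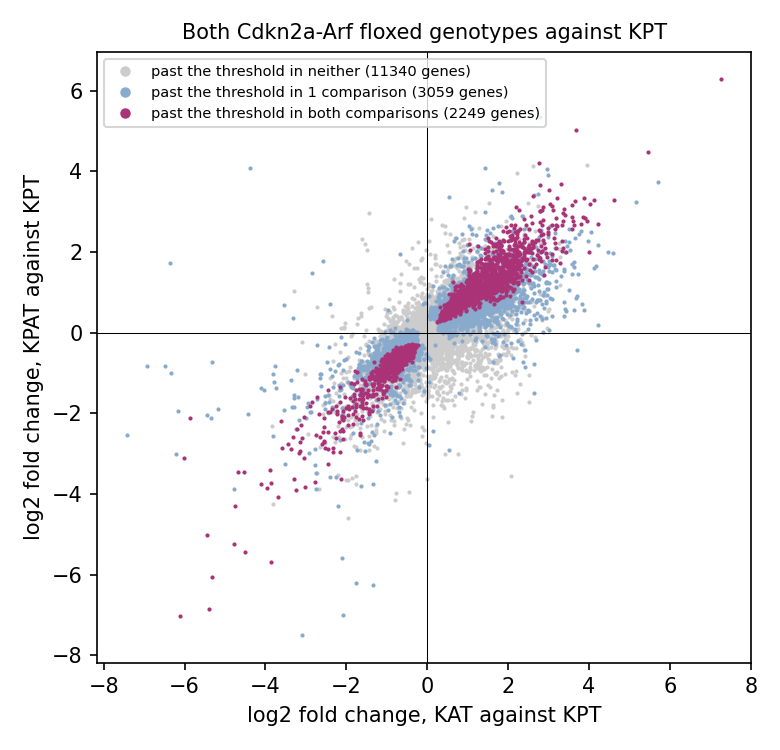
Log2 fold change of each of the 16648 tested genes in KAT against KPT (horizontal) and KPAT against KPT (vertical). Colours mark the 2249 genes past the threshold in both comparisons, the 3059 past it in 1 and the 11340 past it in neither, and the shared KPT libraries add to the slope.

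KPAT against KAT asks what the floxed Trp53 allele adds where Arf is already floxed, and 8 genes passed. Trp53 and Tdg, a DNA glycosylase gene, were lower in KPAT, while Hal, Shbg and 4 pseudogenes were higher. All 8 are named here, Shbg and the pseudogenes Gm9855, Gm13092, Gm15920 and Gm8730 after their values were seen. The count was 7 with edgeR and 306 with DESeq2, and 1798 genes had an unadjusted p below 0.05. It was 36 without KAT 2, 515 with array weights, and 4 on the deposited scale, 2 in each direction. Lower genes outnumbered higher ones without KAT 2 (27 against 9), with array weights (307 against 208) and with DESeq2 (213 against 93).

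Hal, the enzyme that breaks down histidine (chromosome 10, 93488768 to 93519304), was at 11.6 ± 4.92 in KPAT against 0.941 ± 0.712 in KAT (log2 fold change 3.67, SE 0.45, adjusted p = 0.00156). Shbg (chromosome 11, 69614804 to 69617905), a sex hormone carrier gene near Trp53, had 0 reads in all 5 KAT libraries and 1.24 ± 0.422 in KPAT (adjusted p = 1.07e-05). Against a floor of 3 reads per library in KAT, KPAT was at least 8.202-fold and KPT at least 14.1-fold higher. Tdg (chromosome 10, 82629828 to 82650799) was at 24.4 ± 9.35 in KPAT against 56.3 ± 7.001 in KAT (log2 fold change -1.28, SE 0.21, adjusted p = 0.0349). Its call ended in 14 of 35 alternatives (adjusted p up to 0.128). These left out KPT 1, KPT 3, KAT 3, KAT 4, KAT 5, KPAT 1, KPAT 3 or KPAT 5. The call also ended with edgeR, with only these groups fitted and with the replicate block. It ended as well without KPT 1 and KAT 1, without KPT 3, KAT 2 and KPAT 5, and without ribosomal protein genes and processed pseudogenes. Gm9855, a processed copy of Tdg (chromosome 10, 42054113 to 42055306), was at 12.99 ± 4.58 in KPAT and 0.139 ± 0.081 in KAT (adjusted p = 6.43e-08). Gm8730, a copy of Rplp0 (chromosome 8, 102864845 to 102865798), was at 930.2 ± 78.7 against 3.45 ± 0.772 (adjusted p = 0.00301). Gm15920 (chromosome 5, 130188395 to 130188796), a copy of Ndufa12, was at 6.22 ± 2.6 against 0.071 ± 0.045, and Gm13092 (chromosome 4, 150315177 to 150315436), a copy of Snrpf, at 2.48 ± 0.938 against 0.011 ± 0.025. Counts of Tdg and of these copies are uncertain, since reads can move between a gene and its copy.

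**Figure D4:**
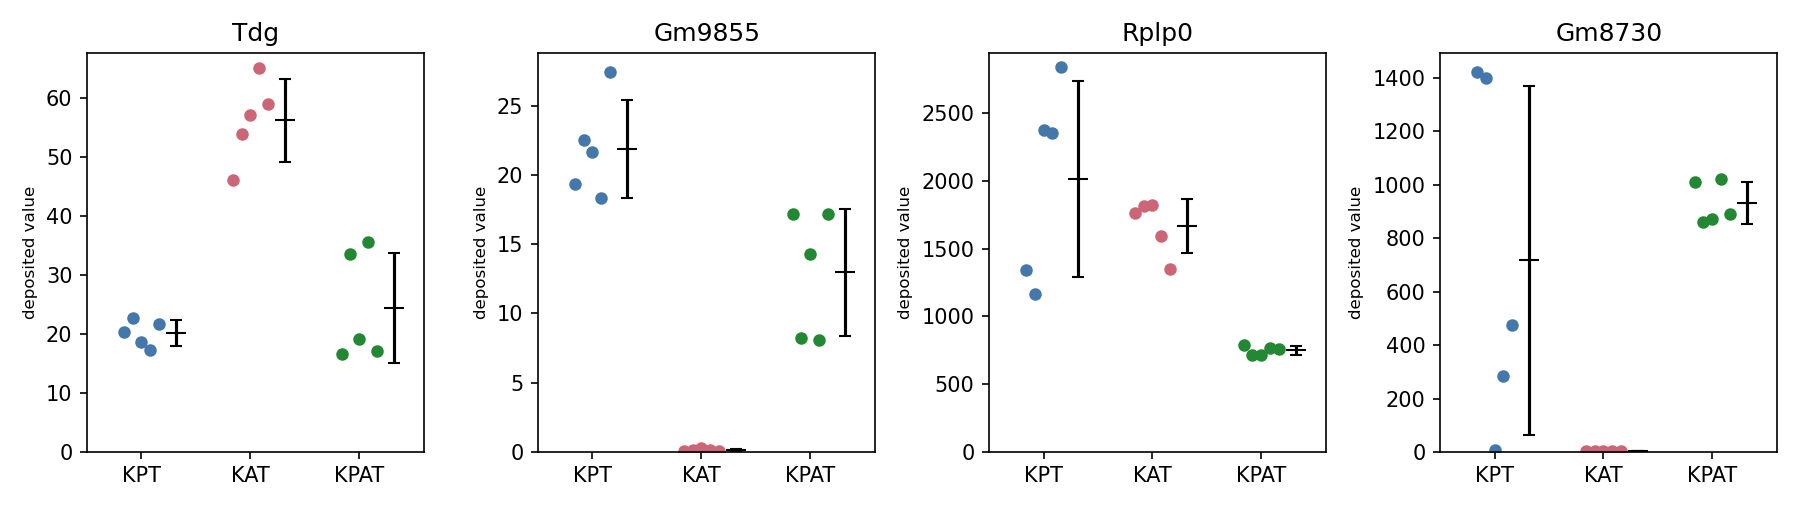
Deposited expression of Tdg and its processed copy Gm9855, and of Rplp0 and its copy Gm8730, each point a tumour and bars the mean ± SD of 5 tumours per genotype. Gm9855 and Gm8730 are near 0 in all KAT tumours, with means of 0.139 and 3.45.

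By camera at the preset correlation, lymphoid and myeloid lists were lower in KPAT than in KAT and the proliferation list higher, with 0 members past the threshold over all genes by limma. Fry called none of these lists, with adjusted p = 0.163 for B and plasma cells, 0.1097 for T cells, 0.0582 for dendritic cells, 0.163 for macrophages and 0.276 for proliferation. The B and plasma cell list was lower (median log2 fold change -2.2, camera adjusted p = 1.46e-11, adjusted p = 0.403 with an estimated correlation), with 11 of 21 genes lower adjusted over the list alone. The T cell list (median log2 fold change -1.81, camera adjusted p = 3.51e-11, adjusted p = 0.403 with an estimated correlation) had 14 of 21 lower adjusted over the list alone, the dendritic cell list (median log2 fold change -1.08, camera adjusted p = 9.74e-07, adjusted p = 0.403 with an estimated correlation) 7 of 15, and the macrophage list (median log2 fold change -0.64, camera adjusted p = 1.05e-07, adjusted p = 0.403 with an estimated correlation) 5 of 24. Ighm, the heavy chain of IgM, was at 10.6 ± 6.23 in KPAT against 354 ± 412 in KAT (log2 fold change -4.11, SE 1.03, adjusted p = 0.185). The co-receptor gene Cd8a was at 0.0797 ± 0.106 in KPAT against 1.69 ± 1.49 in KAT (log2 fold change -3.4, SE 0.88, adjusted p = 0.197). Batf3, a factor of cross-presenting dendritic cells, was at 0.789 ± 0.396 in KPAT against 4.12 ± 2.099 in KAT (log2 fold change -2.25, SE 0.44, adjusted p = 0.0882). Csf1r was at 112 ± 36.7 in KPAT against 206 ± 63.6 in KAT (log2 fold change -0.89, SE 0.24, adjusted p = 0.226). Without KAT 2, whose B and plasma cell level was 4.18 against 7.85 to 8.96 in the other KAT tumours, Ighm was called (-5.06, adjusted p = 0.02505), as was Batf3 (-2.62, 0.0121). The T cell call ended with a stricter minimum level, which left 5 of its genes (median -0.17, adjusted p = 0.222; 7.48e-16 to 0.222 over the alternatives at the preset correlation). Over all alternatives the adjusted p ran from 1.58e-05 to 0.455 for Ighm and from 5.11e-05 to 0.258 for Batf3. The list levels were 3.53 ± 0.6 in KPAT and 5.29 ± 1.11 in KAT (exact two-sided permutation p = 0.0317, 0.254 after adjustment over lists) for T cells and 6.69 ± 0.55 in KPAT and 7.86 ± 0.5 in KAT (exact two-sided permutation p = 0.0238, 0.254 after adjustment over lists) for dendritic cells. For B and plasma cells the level was 5.24 ± 1.24 in KPAT and 7.51 ± 1.91 in KAT (exact two-sided permutation p = 0.0635, 0.317 after adjustment over lists), and for macrophages 9.36 ± 0.47 in KPAT and 9.98 ± 0.31 in KAT (exact two-sided permutation p = 0.0476, 0.317 after adjustment over lists).

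The proliferation list was higher in KPAT (median log2 fold change 0.68, camera adjusted p = 1.00e-10, adjusted p = 0.502 with an estimated correlation), with 1 of 30 genes higher adjusted over the list alone. Rrm2 was at 34.2 ± 17.4 in KPAT against 13.8 ± 1.28 in KAT (log2 fold change 1.18, SE 0.3, adjusted p = 0.188), and the list median was 0.43 without KAT 3. The p53 target list was lower (median log2 fold change -0.21, camera adjusted p = 0.00206, adjusted p = 0.403 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a was at 86.6 ± 26.02 in KPAT against 137 ± 35.97 in KAT (log2 fold change -0.68, SE 0.32, adjusted p = 0.464). Ccng1 was at 83.4 ± 10.1 in KPAT against 119.7 ± 28.2 in KAT (log2 fold change -0.5, SE 0.16, adjusted p = 0.317). The p53 target level was 9.29 ± 0.05 in KPAT and 9.55 ± 0.15 in KAT (exact two-sided permutation p = 0.00794, 0.254 after adjustment over lists), and its call ended with array weights. The antigen presentation list (median log2 fold change -0.73, camera adjusted p = 1.05e-05, adjusted p = 0.652 with an estimated correlation) and the adipocyte list (median log2 fold change -1.89, camera adjusted p = 4.23e-05, adjusted p = 0.403 with an estimated correlation) were lower, 0 of 25 and 3 of 9 genes adjusted over the list alone. Cfd, the adipocyte protease adipsin, was at 0.0747 ± 0.119 in KPAT against 14.1 ± 15.4 in KAT (log2 fold change -5.63, SE 1.61, adjusted p = 0.244), and was called without KAT 2 (-7.24, adjusted p = 0.0253; 0.00285 to 0.553 over all alternatives).

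Further list calls each ended in some analysis that left out 1 library. They were lower for endocrine (median log2 fold change -1.38, camera adjusted p = 0.00412, adjusted p = 0.654 with an estimated correlation), endothelial (-0.39, 0.007601, 0.667), neutrophil (-0.62, 0.01499, 0.652), pericyte (-0.44, 0.01499, 0.654), tuft cell (-0.8, 0.01499, 0.654), mesothelial (-1.08, 0.0437, 0.406), Schwann cell (-0.59, 0.0448, 0.652) and TGF-beta response genes (-0.17, 0.0448, 0.559), the same quantities in the same order. The gastric list was higher (0.45, 0.007601, 0.652). Leaving out KAT 4 left 11 of the 18 list calls of this comparison. Leaving out 1 library ended the endocrine call without KAT 4, KAT 5 or KPAT 3 (adjusted p up to 0.194), the endothelial call without KAT 4 (adjusted p up to 0.217), the neutrophil call without KPAT 5 (adjusted p up to 0.261), the pericyte call without KAT 4, KPAT 4 or KPAT 5 (adjusted p up to 0.0863) and the tuft cell call without KAT 4, KAT 5, KPAT 3 or KPAT 5 (adjusted p up to 0.194). It also ended the mesothelial call without KPT 1, KAT 2, KAT 4, KAT 5, KPAT 3 or KPAT 4 (adjusted p up to 0.146), the Schwann cell call without KPT 5, KAT 3, KAT 4, KAT 5, KPAT 3 or KPAT 4 (adjusted p up to 0.141), the TGF-beta call without KPT 4, KPT 5, KAT 2, KAT 4, KPAT 1 or KPAT 4 (adjusted p up to 0.20) and the gastric call without KAT 3 or KPAT 1 (adjusted p up to 0.12). Among these lists the endocrine median was -0.6 without KPAT 3, -0.87 without KAT 4 and -2.11 without KAT 2. The tuft cell median was -0.52 without KPAT 5 and -1.23 without KPAT 2, and the neutrophil median -0.25 without KPAT 5. Without KAT 4 the endothelial median was -0.22 and the pericyte median -0.29. The TGF-beta median was -0.09 without KPAT 1, and the gastric median 0.23 without KPAT 2.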

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

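Chosen after the results were seen were the tests of epithelial share, of scaling, of library order, of the chromosome 10 variant, and of the summed reads of Rplp0 and of Tdg with their copies. Values were judged within groups of 5 tumours, list levels and single genes on the log2(normalized count + 1) scale. A value was taken up here when its gap to the nearest of the others exceeded 0.71 of the group's range. Chance does this in about 1 in 20 groups. It happened in 24 of 225 groups examined, or 10.7%, of which 13 of 117 were list levels, 11 of 96 single genes and 0 of 12 library measures.

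Among list levels, on the log2 scale, KPT 3 was the lowest KPT tumour for p53 target genes at 8.79 (others 9.25 to 9.36), inflammatory fibroblast genes at 7.29 (others 8.07 to 8.33), TGF-beta response genes at 10.06 (others 10.48 to 10.63) and immediate early genes at 9.99 (others 10.84 to 11.04). KPT 1 was the highest KPT tumour for intestine genes at 10.02 (others 3.45 to 4.42) and gastric genes at 11.38 (others 9.73 to 10.05). KAT 1 was the highest KAT tumour for hypoxia and glycolysis genes at 11.67 (others 9.98 to 10.17). KAT 2 was the lowest KAT tumour for B and plasma cell genes at 4.18 (others 7.85 to 8.96), dendritic cell genes at 6.99 (others 7.98 to 8.25) and Schwann cell genes at 5.99 (others 7.32 to 7.65), and the highest for the chromosome 4 neighbours of Cdkn2a at 9.49 (others 9.04 to 9.13). KPAT 1 was the highest KPAT tumour for type I interferon genes at 9.10 (others 5.37 to 6.42), and KPAT 5 the lowest for neutrophil genes at 4.93 (others 6.24 to 6.53).

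Single genes, judged on the log2 scale, are given here in deposited units. KAT 1 was the highest KAT tumour for Muc3 at 422 (others 0.22 to 1.088), Cdhr5 at 165.8 (others 1.922 to 6.371) and Eno1b at 119.8 (others 0.165 to 0.574). It was the lowest for Psca at 0.469 (others 16.86 to 64.67) and St8sia2 at 0.234 (others 1.654 to 2.715). KPT 3 was the lowest KPT tumour for Cdkn2a at 215.7 (others 304.3 to 335.4) and Sfrp1 at 3.454 (others 21.52 to 43.81), and KPT 5 for Bglap3 at 0 (others 0.378 to 0.881). KPAT 1 was the lowest KPAT tumour for Camk2b at 2.828 (others 14.48 to 24.63), KPAT 3 for Cdhr5 at 0.054 (others 2.616 to 4.224) and KPAT 4 for Eno1b at 0.201 (others 49.87 to 180.2).

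The general fibroblast and macrophage lists were higher in KPAT and KAT than in KPT by camera at the preset correlation. With an estimated one they were not called (adjusted p = 0.492 and 0.583 in KPAT, 0.405 for each list in KAT). A lower share of epithelium would raise the markers of every other cell type alike. The fibroblast level minus the neutrophil level, a pair taken after the neutrophil list was seen to be low, was higher by 2.40 in KPAT than in KPT (SE 0.647, exact permutation p = 0.00794, the smallest the permutations can give, 0.0529 after adjustment over 20 such differences). In KPAT the difference was 1.96 (SE 0.601) for T cells and 1.16 (SE 0.3798) for endothelium, but for macrophages, at 0.89 (SE 0.524), within 2 SE of 0. In KAT it was 2.05 (SE 0.513) for neutrophils and 1.01 (SE 0.389) for endothelium, while dendritic cells (0.05, SE 0.343), B cells (-0.29, SE 0.958), T cells (0.37, SE 0.707) and macrophages (0.44, SE 0.412) lay within 2 SE of the fibroblasts. With the ductal level as a covariate the fibroblast median was 1.76 in KPAT and 1.73 in KAT, both called. None of the 20 differences passed after adjustment (lowest adjusted p = 0.0529 by permutation), and the neutrophil pair was picked from the same data. The differences therefore cannot decide whether a lower share of epithelium is the whole cause. That share stays open as a cause, above all in KAT. The ductal covariate shows only that the fibroblast difference remained with the ductal level held. The scaling between libraries was argued against as the whole cause by a median fibroblast log2 fold change of 1.57 after quantile normalization, KPAT against KPT, and exon length and GC content by 1.48 after their correction. Of the 3 pairs of groups, 0 had overlapping library numbers, so a batch that follows these numbers cannot be told apart from genotype. A change in stroma by genotype may also account for the pattern and was not tested apart from batch.

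The ribosomal protein list was lower in KPAT and KAT than in KPT by camera at the preset correlation, but not with an estimated one (adjusted p = 0.492 and 0.405). The median of the ribosomal protein list, KPAT against KPT, was -0.60 after the exon length and GC correction, -0.65 when each gene's reads were summed with those of its copies, and -0.66 without KPT 3, KAT 2 and KPAT 5, the libraries with the most ribosomal RNA reads. The values argue against length and GC and against those libraries as the whole cause for this list. A length trend was present across protein-coding genes, each group against KPT. Of 345 genes with exons under 1000 bases, 42 were lower and 20 higher in KPAT (median log2 fold change -0.22). In KAT 78 were lower and 36 higher (-0.24). The class with the longest exons had medians of 0.07 in KPAT and 0.08 in KAT. Length as a part of the cause therefore stays open. The summed reads cannot decide on shared reads, since reads with several places in the genome may have been dropped from gene and copy. A batch by library number, with 0 of 3 pairs overlapping, cannot be told apart from genotype, which may also be the source and was not tested separately. Of 363 processed pseudogenes, 49 were lower and 5 higher in KPAT (median log2 fold change -0.57), and 109 lower and 5 higher in KAT (-0.67). The others did not pass, and this class was neither tested as a set nor weighed against these explanations.

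Several processed pseudogenes were present in some mice and near 0 in others, among them Gm9855, a copy of Tdg, and Gm8730, a copy of Rplp0. Over the 114 of 636 copies that varied at least 8-fold, the median Spearman correlation of copy and parent was 0.26 across the 15 libraries. It lay within the 0.10 to 0.32 of 100 random pairings, so copy and parent showed no opposite course in general. Single pairs ran from -0.86 (Gm8210 and Rpl29) to 0.96 (Gm5559 and Gapdh), with 38 below 0 and Gm9855 and Tdg at -0.70. The median cannot exclude moving reads in some pairs, nor detect them where the parent has many more reads than its copy. For Rplp0, the summed log2 fold change with Gm8730 was 0.01, KPAT against KAT, against -1.15 for Rplp0 alone, which is consistent with reads shared between them. For Tdg, the sum with Gm9855 still differed by -0.59 (SE 0.117), against -1.28 for Tdg alone. The treatment of reads with several places in the genome is not given. If such reads were dropped, tumours with the copy would lose reads from the sum as well. The sum therefore cannot decide whether reads shared with Gm9855 make the whole difference of Tdg. How much of it is shared reads and how much a change of Tdg stays open. A strain variant on chromosome 10, where Tdg and the parents of Gm13092 and Gm15920 lie, cannot be told apart from other causes. Within KPAT, 6% of 1000 random triples of copies varied together as closely as these 3 copies. Ranks within KPAT cannot test a difference that separates KAT from the other groups. Hal, higher in KPAT than in KAT, lies on the same chromosome (93488768 to 93519304) near Snrpf (93583029 to 93589706), so the same limit holds for it.

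Other splits of the same 10 tumours into 5 and 5 were drawn 100 times per comparison, the real split included. For KPAT against KPT, 1 of 100 splits gave as many genes as the real 2752, with 494 the highest of the others, and for KAT against KPT 1 of 100 gave as many as 4805, with 197 the highest other. Chance is excluded at 0.05 in both. For KPAT against KAT, 4 of 100 splits gave at least the real 8 genes, a share under 0.05. Another split called 111, while 88 of the other splits called no gene. Whether a structure of the samples beside genotype gave the 111 was not tested.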

How the results depend on the processing

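Alternatives chosen after seeing the data were the deposited scale, the exon length and GC correction, both removals of several tumours and the removal of ribosomal protein genes and pseudogenes. The 8 genes of KPAT against KAT became 17 after quantile normalization, 15 with only these groups fitted, 515 with array weights, 65 with the ductal covariate, 4 on the deposited scale, 17 without KPT 3, KAT 2 and KPAT 5, 3 without ribosomal protein genes and pseudogenes (fewer genes tested) and 306 with DESeq2. The 2752 genes of KPAT against KPT became 1811 with only these groups fitted and 1735 without KPT 3, KAT 2 and KPAT 5 (fewer samples). The 18 lists of KPAT against KAT became 11 on the deposited scale and 0 with fry, whose lowest adjusted p was 0.0582. With the correlation estimated, 0 lists were called in each comparison (lowest adjusted p 0.492, 0.405 and 0.403 for KPAT against KPT, KAT against KPT and KPAT against KAT). The 2249 shared genes became 1489 without KPT 1 and KAT 1, 1499 without KPT 3, KAT 2 and KPAT 5, and a median of 707.5 with KPT split (fewer samples). Where no reason is given, the cause was not tested. Results that reversed in KAT against KPT were Cdkn2a, not called in either direction (-0.45 with array weights, -0.80 with the ductal covariate, -0.10 without KPT 3, KAT 2 and KPAT 5), and the medians of the gastric (0.13) and type I interferon lists (0.65) with the ductal covariate, and the cause was not tested. The type I interferon median of KPAT against KPT also turned positive there (0.22), though camera's direction did not.

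Leaving out 1 library gave 1686 (without KPAT 2) to 2896 genes for KPAT against KPT, 3553 to 4836 for KAT against KPT, and 7 to 36 (without KAT 2) for KPAT against KAT. The lists called ranged from 13 to 20, from 22 to 24 and from 11 (without KAT 4) to 23, and the shared genes from 1463 (without KPAT 2) to 2311. In all 15 such fits, 60 of 83 named genes kept their side of the threshold in KPAT against KPT, 85 of 95 in KAT against KPT and 22 of 28 in KPAT against KAT, as did 11 of 15, 19 of 24 and 8 of 18 list calls. Over all alternatives these were 48, 72 and 11 genes, and over those that test lists at the preset correlation 9, 15 and 6 lists. Of 2874 gene values recomputed for KPAT against KPT, 304 lost the threshold, as did 89 of 3287 for KAT against KPT and 14 of 961 for KPAT against KAT, where 41 gained it. Of list values at the preset correlation, 19 of 480, 33 of 767 and 55 of 573 lost it.

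With the replicate number as a block, 2248, 4313 and 7 genes and 16, 24 and 17 lists were called. The numbers do not pair the mice: deviations of same-numbered tumours correlated from -0.21 to 0.25 (median 0.05, 15 pairs), and 5 of 15 tumours correlated best with their own number. Depth limits low genes such as Shbg, with 0 reads in 5 KAT libraries.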

Other observations

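Several genes changed in lists that were not called as a whole. Of all tested genes, 16.5% passed in KPAT against KPT and 28.9% in KAT against KPT. Member counts in this section that lie near these shares are therefore no result about a list. The inflammatory cytokine list was not called (camera adjusted p = 0.50 in KPAT and 0.166 in KAT, each against KPT), with 3 of 27 genes higher and 1 lower in KPAT and 6 higher and 1 lower in KAT. Csf1, the growth factor of macrophages, was at 46.3 ± 16.1 in KPAT against 21.1 ± 4.46 in KPT (log2 fold change 1.1, SE 0.23, adjusted p = 0.00803), and at 54.4 ± 15.4 in KAT against 21.1 ± 4.46 in KPT (log2 fold change 1.35, SE 0.23, adjusted p = 0.001098). The monocyte chemokine gene Ccl2 was at 15.2 ± 8.23 in KPAT against 2.86 ± 2.28 in KPT (log2 fold change 2.62, SE 0.61, adjusted p = 0.01198), and the related Ccl8 at 11.7 ± 9.15 in KAT against 1.37 ± 0.7202 in KPT (log2 fold change 2.78, SE 0.53, adjusted p = 0.00194). Of 28 p53 target genes 4 rose and 1 fell in KPAT against KPT (camera adjusted p = 0.708). Ak1 was at 47.2 ± 14.8 in KPAT against 16.4 ± 3.26 in KPT (log2 fold change 1.48, SE 0.21, adjusted p = 0.00174) and Pmaip1, which encodes the apoptosis protein Noxa, at 48.6 ± 18.5 in KPAT against 168 ± 60.5 in KPT (log2 fold change -1.82, SE 0.34, adjusted p = 0.00508). Ak1 was thus higher than in KPT in both groups, while Trp53 was floxed in KPAT.

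Of 12 mesothelial genes 4 rose in KAT against KPT (camera adjusted p = 0.0732), with the mucin gene Muc16 at 7.43 ± 6.21 in KAT against 1.09 ± 1.31 in KPT (log2 fold change 2.95, SE 0.65, adjusted p = 0.00437). Of 9 Schwann and nerve genes 4 rose (0.148), with the sodium channel gene Scn7a at 33 ± 22.7 in KAT against 5.29 ± 2.56 in KPT (log2 fold change 2.4, SE 0.62, adjusted p = 0.0114). Siglecf, a receptor of eosinophils, was at 9.96 ± 7.38 in KAT against 1.63 ± 0.899 in KPT (log2 fold change 2.37, SE 0.66, adjusted p = 0.0154). It alone rose in a list of 8 mast cell and eosinophil genes (camera adjusted p = 0.356). Siglecf is also a member of the tuft cell list, which camera called higher in KAT at the preset correlation. Sprr1a, a squamous envelope gene, was at 27.3 ± 18.9 in KPAT against 162 ± 54.4 in KPT (log2 fold change -2.75, SE 0.57, adjusted p = 0.007595), and at 20.5 ± 22.4 in KAT against 162 ± 54.4 in KPT (log2 fold change -3.44, SE 0.57, adjusted p = 0.000916), while the basal-like list of 17 genes was not called (0.213 and 0.166). Igfbp5, a growth factor binding protein gene of the senescence list, was at 471 ± 311 in KPAT against 111 ± 71.3 in KPT (log2 fold change 2.21, SE 0.48, adjusted p = 0.00887), with that list not called (0.708). Among 7 chromosome 4 neighbours of Cdkn2a, Hacd4 was at 23.2 ± 7.87 in KAT against 11 ± 2.33 in KPT (log2 fold change 1.03, SE 0.24, adjusted p = 0.00664) and Mllt3 at 37.8 ± 4.72 in KAT against 55.6 ± 7.63 in KPT (log2 fold change -0.55, SE 0.13, adjusted p = 0.00566).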
